A study of Mus musculus with 4 samples.

How the data were processed

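Single nuclei from mouse placentas collected at embryonic day 12.5 were profiled by droplet 3' RNA sequencing. There were 4 groups with 1 library each: a Dnmt3b knockout (KO), the wild type of the same cross, a conditional knockout made with Sox2-Cre (cKO), and the wild type of that cross. Per the labels' protocols, each mutant was processed in parallel with the wild type of its own cross, 10000 DAPI-stained nuclei per sample were flow sorted, and libraries were multiplexed for sequencing. How many placentas entered a library is not given in the labels.

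The deposited values are whole-number UMI counts per gene and nucleus, one filtered matrix per library. Per the submitters' processing notes, reads were processed with bcl2fastq and Cell Ranger 6.0.0 against the mm10 build. Whether intronic reads were counted, and which annotation release was used, is not given in the sources used here. Of the 32285 feature IDs in the files, 32158 were found in GENCODE vM21 on GRCm38, which supplied the coordinates, and that release may differ from the one the authors counted against. Gene symbols are those of the files.

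Nuclei with at least 300 detected genes were kept, and doublets were then marked in each library with scrublet, as run by scanpy 1.11.5, at an expected rate of 6%, and removed. The marked nuclei were 238 in the KO library, 250 in its wild type, 241 in the cKO library and 386 in its wild type. These were 4.73%, 4.52%, 3.46% and 5.30% of nuclei with at least 300 genes. The libraries were integrated with Seurat 5.3.0 in R 4.3.3 by reciprocal principal components, with 3000 variable genes per library, 2000 integration features and 30 components. Nuclei were clustered by the Leiden method (igraph 0.11.9 and leidenalg 0.10.2) on 20 nearest neighbours at resolution 1. The germline list, Dnmt3b, Xist, Tsix, Y-linked genes, Malat1, Neat1, Gm42418, Gm26917, mitochondrial genes and ribosomal protein genes were kept out of the clustering, so that a difference in them could not form a cluster.

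Clusters were named from 19 marker sets chosen before the data were examined, as were the gene lists, the rule for naming genes and the first set of alternative settings below. A cluster took the name of the set with the highest score, which had to reach 1 with at least 3 detected markers, and was left unnamed where its depth was low with none of the set's markers among its 10 leading genes. Trophoblast, endothelial and mesenchymal clusters were told apart as fetal or maternal by their level of Y-linked genes. That level was taken over the libraries that held Y-linked reads, so the cKO library did not enter. Nuclei of the cKO library took the origin that the other libraries gave their cluster. Clusters that met these conditions were joined into classes. In trophoblast, clusters 11 and 17 met them, but their leading genes held more markers of another trophoblast set than of their own, so they count in the class and are given by number. The comparisons used trophoblast, fetal endothelium and mesenchyme together (below called fetal mesoderm), and decidual stroma, which is maternal. Cell types are rebuilt names, since the files hold no annotation.

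UMIs were summed per library and class and divided by the class total and scaled to CPM. Log2 ratios used a prior count of 0.5 scaled to depth, over genes with at least 50 UMIs in the pair, or 20 for members of gene lists. With 1 library per group no test between genotypes is possible, so no p-value is given. Sums of UMIs have exact Poisson intervals, ratios exact conditional intervals, shares exact Clopper-Pearson intervals, and medians of lists intervals from 1000 Poisson resamples, at the 95% level. These intervals, and the floor of 3 UMIs per library used for genes at 0, cover counting error only. The yardstick was the wild type of the KO cross over the wild type of the cKO cross. The median of each list was ranked among 10000 random lists of the same size, matched in 20 bins on UMIs pooled over the pair, as a description of these libraries. Members were counted as up or down at 1.5-fold by their own ratio, without subtracting the median of all genes.

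Named genes needed a CPM ratio of at least 2-fold, a mutant level beyond the wild type of the other cross by at least 1.5-fold in the same direction, and the same direction in at least 0.75 of the clusters holding 10 or more UMIs of the gene. The 12 largest ratios up and down were taken for the KO in trophoblast, and 8 up and down elsewhere. Predicted genes, mitochondrial, ribosomal protein, globin, Xist, Tsix and Y-linked genes were left out of the ranking. The Y-linked list used for this held 4 genes, so other Y-linked genes passed. In addition, Dnmt genes and the 4 members with the largest absolute log2 ratio of each list were eligible.

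The 22 lists were germline genes (46 symbols), DNA methylation machinery, Rhox homeobox genes, maternally and paternally expressed imprinted genes, clustered protocadherins, cadherins and integrins, extracellular matrix, the prolactin family, pregnancy-specific glycoproteins and Ceacams, placental cathepsins, syncytium formation, nutrient transport, angiogenesis, hypoxia response, interferon response, proliferation, genes of the early totipotent embryo, immediate early and heat shock genes, mitochondrial transcripts, Y-linked genes and globins. The last 4 served as signs of handling, cytoplasmic RNA, fetal sex and red cell RNA.

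The first set of alternative settings was a minimum of 500 genes per nucleus, no doublet removal, clustering without integration, Leiden resolutions of 0.5 and 2, TMM factors from edgeR 4.0.16 on the class sums, a minimum of 1 UMI over the pair, a prior count of 2, ratios standardised to the pooled cluster mix, and nuclei thinned to 1000 UMIs each. Alternatives chosen after seeing the data were shares of fetal nuclei, totals without Malat1 and Gm42418, list members on autosomes alone, and labyrinth clusters grouped within trophoblast. Statistics ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

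The calculation was tested on simulated counts with known folds. The simulated depth was 25% of the counts of each whole library of the KO pair, all nuclei included. Over 13863 genes, all simulated 4-fold increases (100%) and 0% of 1.5-fold increases passed the 2-fold rule. So did 52.9% of true 2-fold increases and 0.0731% of unchanged genes. Both simulated libraries were drawn by Poisson counting from the pooled profile of the pair, so variation between libraries was left out. Between the real wild types, 11.6% of trophoblast genes were at least 2-fold higher and 1.35% at least 2-fold lower, with the shift of all genes included. KO fetal mesoderm, at 556153 UMIs, was also far shallower than the simulated libraries. A list of 35 genes among 16257, raised 2-fold, had a median log2 ratio of 0.98, above 100% of its random lists.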

Results

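Nuclei of mouse placenta at mid-gestation (E12.5) were compared between Dnmt3b mutants and wild types. Dnmt3b is a de novo DNA methyltransferase. In the KO the gene was lost from every fetal and placental lineage. In the cKO it was lost through Sox2-Cre, which is active in cells derived from the epiblast, the source of the fetus and of fetal vessels and mesenchyme in the placenta, and not in trophoblast. Decidua is maternal tissue and carries the mother's genotype. There was 1 library per group, so no value has a replicate check. The KO library held 5034 barcodes and 46212216 UMIs, and its wild type 5533 barcodes and 44024031 UMIs. The cKO library held 6995 barcodes and 22507637 UMIs, and its wild type 7290 barcodes and 30510404 UMIs. After filtering, 4796, 5283, 6728 and 6900 nuclei were kept, in the same order, in 27 clusters. Trophoblast nuclei gave 12667822, 16337884, 8516997 and 15452818 UMIs, and fetal mesoderm, meaning fetal endothelium, mesenchyme and smooth muscle, gave 556153, 1675895, 1160172 and 1763744.

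Dnmt3b transcripts were present in every library. In trophoblast they stood at 26.2 CPM in the KO against 15.9 CPM in its wild type, and at 13.2 CPM in the cKO against 16.4 CPM. In fetal mesoderm 19 and 33 UMIs were counted in the KO pair, and 15 and 26 in the cKO pair. The labels do not say which exons were deleted, and a 3' tag outside the deleted part checks nothing, so these counts do not test the genotypes. The cKO pair differed in fetal sex. Y-linked genes gave 4 UMIs in the fetal classes of the cKO library against 5657 in its wild type. Xist, the RNA that coats the inactive X chromosome, stood at 2779 CPM in cKO trophoblast and 21.7 CPM in its wild type. Both libraries of the KO pair held Y-linked transcripts, with Xist at 66.9 CPM in KO trophoblast and 36.7 CPM in its wild type. Genotype and sex therefore cannot be separated in the cKO pair.

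The first comparison asked how loss of Dnmt3b in all lineages altered the make-up of the placenta. Fetal mesoderm made up 2.27% of nuclei in the KO library (95% interval 1.87 to 2.74) and 5.32% in its wild type (4.73 to 5.96). Trophoblast made up 22.0% (20.9 to 23.2) and 28.9% (27.7 to 30.1), and maternal decidual stroma 46.1% (44.7 to 47.6) and 25.6% (24.5 to 26.8). Fetal nuclei here mean trophoblast, fetal mesoderm and extraembryonic endoderm, so erythroid and unnamed nuclei are left out. Counted among fetal nuclei alone, a denominator chosen after seeing the data, the order for trophoblast turned. It made up 74.6% (72.2 to 76.8) in the KO and 66.9% (64.9 to 68.8) in its wild type. With a minimum of 500 genes per nucleus these shares were closer, at 76.6% and 71.8%. Fetal mesoderm stayed lower among fetal nuclei, at 7.70% (6.36 to 9.21) and 12.3% (11.0 to 13.7). Extraembryonic endoderm made up 17.7% and 20.8% of fetal nuclei. Clusters whose best marker set was of the labyrinth, the exchange zone of the placenta, made up 26.8% of KO trophoblast (24.1 to 29.6) and 29.1% of its wild type (26.8 to 31.4), a difference not detectable at this depth. They include cluster 11, whose name was not upheld, in a grouping formed after the clusters were seen. Within fetal mesoderm, mesenchyme-like nuclei made up 56.0% in the KO and 36.3% in its wild type, and smooth muscle-like nuclei 15.6% and 32.7%. The wild types of the crosses differed in trophoblast by more than either mutant did from its own wild type, at 28.9% and 54.5% of nuclei. The same held for fetal mesoderm, at 5.32% and 10.6% of nuclei in the wild types. Among fetal nuclei, fetal mesoderm stood closer in the wild types, at 12.3% and 14.1%. Shares also depend on dissection, on the sort of nuclei and on depth. With a minimum of 500 genes per nucleus, the trophoblast difference of -6.89 percentage points became -12.6. Unnamed nuclei then fell from 323 to 108 in the KO and from 666 to 135 in its wild type. Nuclei named as trophoblast rose from 1056 to 1169 and from 1527 to 1911, so the naming of clusters took part in this move.

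**Figure D1:**
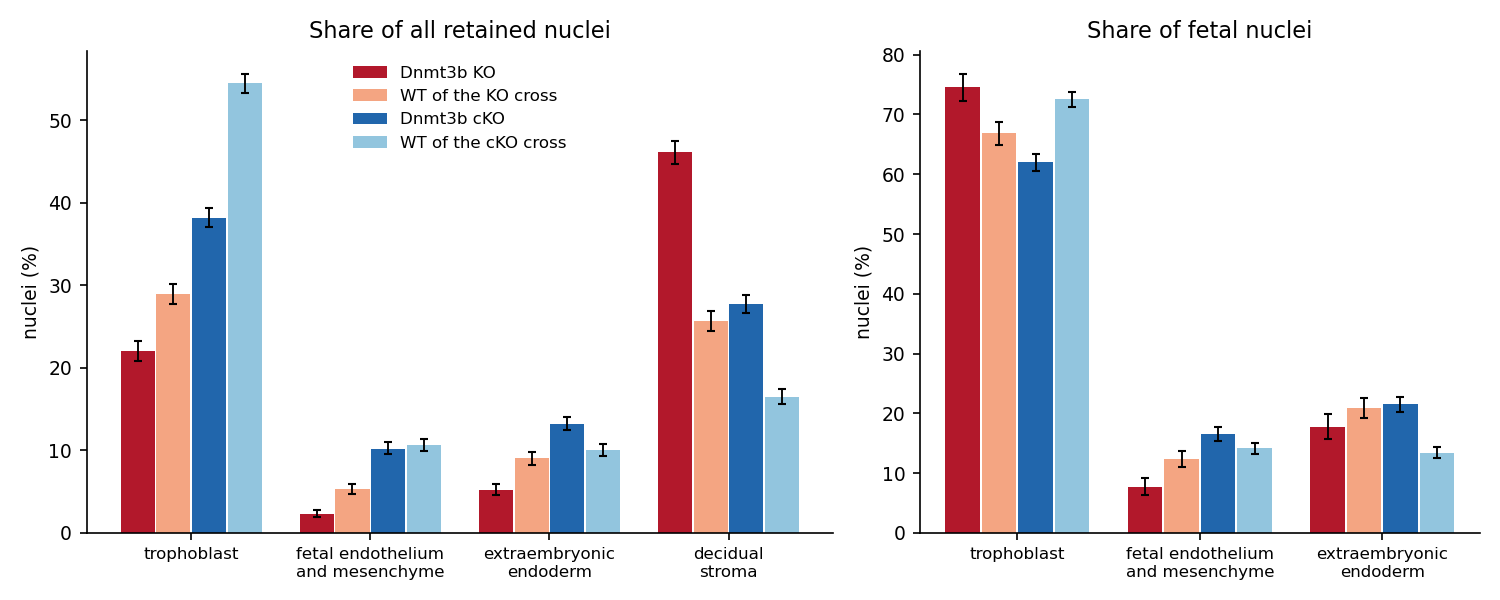
Percent of all retained nuclei and of fetal nuclei in each cell class, as bars with exact 95% binomial intervals, for the KO library, the cKO library and the wild type of each cross. Decidual stroma held 46.1% of nuclei in the KO library and 25.6% in its wild type.

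In KO trophoblast, genes of the germline were higher as a group. Dazl, an RNA-binding protein of germ cells (ENSMUSG00000010592, chromosome 17, 50279395 to 50293636 on GRCm38), gave 1189 UMIs in the KO and 6 in its wild type, or 93.9 and 0.367 CPM, a 256-fold difference (117 to 698). Asz1, of the piRNA pathway, was 17.9-fold higher (14.2 to 22.9), Sycp1, of the synaptonemal complex of meiotic chromosomes, 13.8-fold (10.2 to 18.9), and Sohlh2, a transcription factor of spermatogonia and oocytes, 34.1-fold (20.4 to 61.6). Of 35 measured germline genes, 20 were at least 1.5-fold higher and 2 at least 1.5-fold lower. Their median log2 ratio was 0.86 (0.70 to 1.15), above 100% of matched random lists, against 0.50 (0.32 to 0.58) between the wild types, or 0.81 and 0.13 relative to the median of all genes. Another member, 1700013H16Rik, gave 1039 and 3 UMIs, and with members on autosomes alone, an alternative chosen after seeing the data, the median was 1.53. A Dazl UMI was found in 46.6% of KO trophoblast nuclei (43.5 to 49.7) and in 0.393% of its wild type. In KO decidua, which is maternal and picks up free fetal RNA, the share was 2.67%, at a median depth of 9700 UMIs against 9446 in KO trophoblast. With nuclei thinned to 1000 UMIs, which left out 317 KO nuclei and 567 of its wild type, the shares in KO trophoblast and decidua were 8.17% and 0.498%. Dazl stood at 61.1 to 192 CPM across the trophoblast clusters, and in all 9 of them its interval lay above that of the wild type.

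Several genes outside the germline list also stood far apart between KO trophoblast and its wild type. Poteg was 154-fold higher (95.9 to 265), with 2028 against 17 UMIs, and the X-linked Pet2 149-fold, with 347 against 3. Wdr49 was 34.1-fold higher, Krt14, a keratin of basal epithelia, 23.0-fold and Ccdc172 20.3-fold. The Y-linked genes Zfy1, Usp9y and Uba1y were 65.6-fold, 54.7-fold and 30.4-fold higher, while the 4 listed Y-linked genes had a median log2 ratio of 0.16. Dlk1, a paternally expressed imprinted gene of chromosome 12 (109452823 to 109463336), gave 1 UMI in the KO and 54 in its wild type, 41.9-fold lower (7.20 to 1684). Its wild-type level was 3.31 CPM in trophoblast and 417 CPM in fetal mesoderm. With doublets kept the log2 ratio of Dlk1 was -3.62 in place of -4.88. Ush2a was 17.7-fold lower, the transcription factor gene Neurog2 10.1-fold, the semaphorin receptor gene Plxna4 9.56-fold, and Lgr5, a Wnt-pathway receptor that marks stem cells in several tissues, 7.75-fold. Slit1 also ranked among the lower genes, and it is among the leading genes of cluster 17, a trophoblast cluster whose share differed. The median absolute log2 ratio over 13790 genes was 0.214, where counting alone gave 0.0711, and 0.434 over 13486 genes between the wild types. The value between the wild types includes a shift of all genes, whose median log2 ratio was 0.36, against 0.05 in the KO pair.

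**Figure D2:**
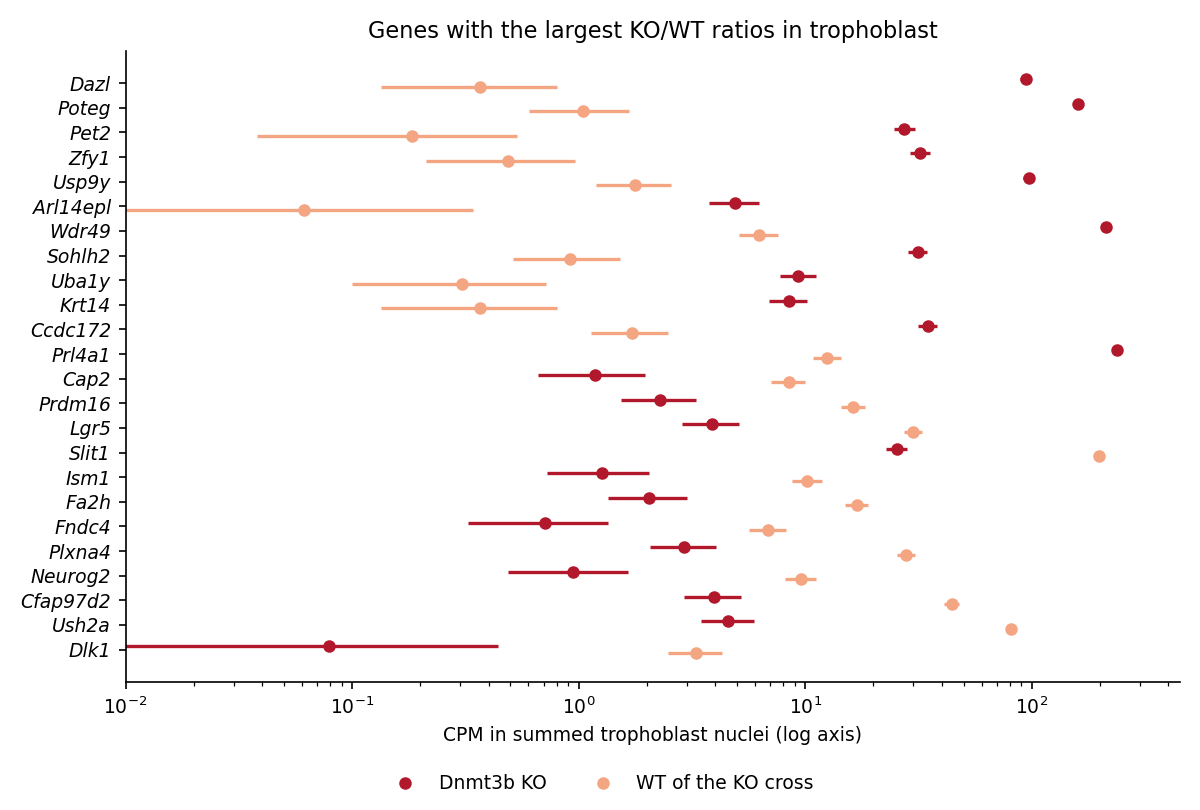
CPM in summed trophoblast nuclei, on a log axis, of the ranked genes with the largest ratios up and down, with 1 point for the KO and 1 for its wild type and exact 95% Poisson intervals as lines, which run off the axis for Arl14epl and Dlk1. Dazl lay at 93.9 CPM in the KO and 0.367 CPM in its wild type.

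Hormone and glycoprotein families of trophoblast differed in opposite directions in the KO. Placental prolactins were higher, with 14 of 23 at least 1.5-fold up, 5 at least 1.5-fold down and a median log2 ratio of 0.93 relative to all genes, against 0.17 between the wild types. Prl4a1 was 19.1-fold higher (16.6 to 22.1), Prl5a1 5.80-fold and Prl2c1 4.38-fold, while Prl8a6 stood at 0.153 of its wild type. Prl4a1 is in the marker set of parietal trophoblast giant cells, and the cluster of that name held 15.7% of KO and 10.2% of wild-type trophoblast. Pregnancy-specific glycoproteins and Ceacams were lower, with 14 of 24 down and 5 up and a median of -0.78, against 0.12 between the wild types, including Psg26 at 0.257 and Psg21 at 0.378. Several of these are among the leading genes of cluster 17, which held 10.5% of KO and 18.3% of wild-type trophoblast, and with the cluster mix standardised the median was -0.22. Placental cathepsins had a median of -0.72 over 6 genes, or -0.26 so standardised, against -0.57 between the wild types, with Ctsq at 0.219 and Cts8 16.3-fold higher. Members of these families share sequence, so reads can be split among them. Immediate early and heat shock genes were higher, at a median of 0.85 with 9 of 11 up, among them Fosb at 2.71-fold, as were mitochondrial transcripts at 0.42. Globin RNA was lower, at -0.86 with 5 of 7 down. These signs of handling and of RNA from other cells differed between the same libraries as every list above.

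Among imprinted genes, the noncoding transcripts Meg3, Rian and Mirg, expressed from the maternal chromosome, were 2.37-fold, 3.09-fold and 6.42-fold higher in KO trophoblast. The maternally expressed list had a median of 0.19 relative to all genes, with 7 of 22 up and 2 down, and the paternally expressed list -0.08, with 2 of 26 up and 6 down. Fkbp6, on both the paternal and the germline list, was 6.57-fold higher, and Snrpn 3.20-fold. Extracellular matrix genes had a median of 0.26, with 5 of 24 up and 3 down, and cadherins and integrins 0.13, with 5 of 24 up and 1 down. Syncytium formation genes stood at -0.23, with Gcm1, the transcription factor of the second syncytial layer, at 0.549 of wild type, and hypoxia response genes at -0.19. The wild types differed by -0.38 in syncytium and -0.48 in hypoxia genes, -0.37 in extracellular matrix, -0.10 in cadherins and integrins and -0.22 and -0.39 in maternally and paternally expressed genes. The medians of the other lists lay near all genes, at 0.03 for DNA methylation machinery, -0.03 for clustered protocadherins, -0.04 for nutrient transport, 0.05 for angiogenesis, -0.08 for interferon response and 0.12 for proliferation. Rhox genes, 4 measured, stood at -0.15 and genes of the early totipotent embryo, also 4, at 0.35.

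KO fetal mesoderm showed a still higher germline signal together with interferon-response genes. Sycp1 was 161-fold higher (43.6 to 1348), with 107 against 2 UMIs, Tex11, a meiotic gene, 51.2-fold (13.1 to 440) and Asz1 24.1-fold. The wild types differed widely in Tex11. It stood at 61.1 CPM in the KO and 1.19 CPM in its wild type, from 2 UMIs, but at 14.2 CPM in the wild type of the cKO cross. Of 16 measured germline genes, 14 were up and 0 down by 1.5-fold, and their median log2 ratio was 2.06 (1.71 to 2.52) against 0.44 between the wild types. Dazl gave 16 UMIs against 1. Interferon-response genes had a median of 1.32 relative to all genes (1.08 to 1.63), with 11 of 14 up and 0 down, against 0.34 between the wild types. Examples were Ifi44 at 8.04-fold, Rsad2 at 5.74-fold, Ifit1 at 4.22-fold and Isg15 at 4.11-fold. Hypoxia-response genes stood at 0.71, with 7 of 11 up and Vldlr at 2.92-fold, and extracellular matrix genes at 0.35, with Tnc 4.98-fold and Col1a1 4.45-fold higher. Meg3 was 2.15-fold higher and Dlk1 stood at 0.332 of wild type.

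Among single genes of KO fetal mesoderm, Smoc2 was 12.1-fold higher (6.89 to 22.3), Fras1, of basement membranes, 8.32-fold and Col4a6 6.93-fold. Brinp1 was 15.5-fold lower, Cdh6, a cadherin, 11.6-fold and Egfem1 9.02-fold. Egfem1 leads the smooth muscle-like cluster and Smoc2 a decidual cluster, and with the mesoderm mix standardised the log2 ratio of Egfem1 was -1.74 in place of -3.14. Stmn2 gave 0 UMIs in the KO and 58 in its wild type, at least 6.42-fold lower. Trophoblast transcripts were also lower here, with cathepsins at -1.92 and pregnancy-specific glycoproteins at -1.14 relative to all genes, where the wild types differed by -0.78 and -1.02. Prolactins stood at -0.25, or 1.36 with doublets kept. Signs of handling and of red cells were higher, with immediate early genes at 0.75, mitochondrial transcripts at 0.42 and globins at 0.90. The remaining medians were -0.10 for DNA methylation machinery, -0.46 for Rhox genes, 0.15 and -0.04 for maternally and paternally expressed imprinted genes, 0.19 for protocadherins, -0.39 for cadherins and integrins, -0.17 for syncytium formation, -0.14 for nutrient transport, 0.00 for angiogenesis, 0.17 for proliferation and 0.17 for Y-linked genes. The class held 109 KO nuclei, which limits the depth.

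**Figure D3:**
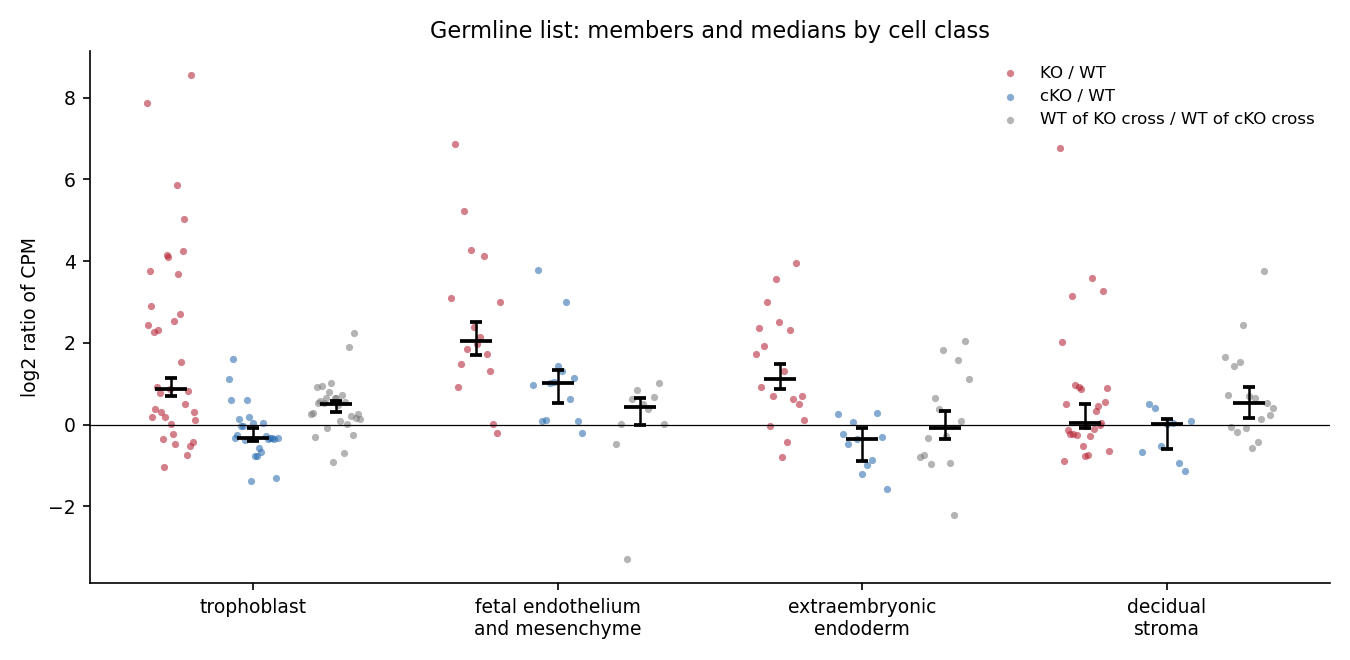
Log2 ratios of germline genes, mutant over its own wild type and wild type over wild type, in 4 cell classes, with 1 point per gene, medians as bars and 95% resampling intervals. In trophoblast and fetal mesoderm the medians were 0.86 and 2.06 for the KO, and -0.32 and 1.03 for the cKO.

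The second comparison asked which effects remained when trophoblast kept Dnmt3b. In cKO fetal mesoderm the germline genes were higher as a list, and in cKO trophoblast the list was not. In fetal mesoderm Sycp1 was 15.6-fold higher (5.64 to 59.9), with 41 against 4 UMIs, and Slc25a31, an ADP/ATP carrier of germ cells, 9.12-fold (3.13 to 36.2). Asz1 was 8.36-fold higher (1.82 to 77.6), with 11 against 2 UMIs. Hsf2bp, of meiotic recombination, was 6.59-fold higher (1.81 to 36.0), with 13 against 3 UMIs. Asz1 and Hsf2bp fell below the minimum of UMIs for list members, so they are not among the 13 measured. Of 13 measured members 9 were up and 0 down by 1.5-fold. Their median log2 ratio was 1.03 (0.53 to 1.35), or 1.22 relative to all genes, against 0.21 between the wild types. In thinned nuclei 7 members were measured in the cKO pair, with a median of 1.08 relative to all genes, and 3 between the wild types. In trophoblast 4 of 25 members were up and 5 down, with a median of -0.32 (-0.40 to -0.08), or -0.02 relative to all genes. Dazl gave 8 UMIs in cKO trophoblast and 4 in its wild type, or 0.939 and 0.259 CPM, a ratio of 3.63 (0.97 to 16.5). Sycp2, of the synaptonemal complex, was 3.08-fold higher in cKO trophoblast (2.27 to 4.20) and Ddx4 2.19-fold (1.35 to 3.55). Asz1 stood there at 0.384 of wild type (0.248 to 0.577). Relative to TMM, log2 ratios of total-count CPM were shifted by -0.28 for all genes in cKO trophoblast, -0.17 in cKO fetal mesoderm, 0.10 in KO fetal mesoderm, and 0.35 in trophoblast between the wild types.

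In the cKO library trophoblast made up 38.2% of nuclei (37.1 to 39.4) and in its wild type 54.5% (53.3 to 55.7), or 62.0% and 72.5% of fetal nuclei. Fetal mesoderm stood at 10.2% (9.50 to 11.0) and 10.6% (9.88 to 11.3), a difference not detectable at this depth, and decidua at 27.8% and 16.5%. Y-linked genes could not check whether the cKO nuclei of fetal mesoderm are fetal. Among fetal nuclei, fetal mesoderm made up 16.6% in the cKO (15.4 to 17.7) and 14.1% in its wild type (13.2 to 15.1). Endoderm made up 13.2% and 10.0% of all nuclei, or 21.5% and 13.4% of fetal nuclei. The same labyrinth grouping, cluster 11 included, held 39.6% of cKO trophoblast (37.7 to 41.6) and 32.6% of its wild type (31.1 to 34.1). Gm42418, a transcript with ribosomal RNA sequence, took 13.3% of cKO counts and 7.83% of its wild type, and the median depth per nucleus was 2453 and 3122 UMIs.

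With Xist and the listed Y-linked genes left out, the largest ratios in cKO trophoblast were smaller than those in the KO. Eif3j2 was 11.9-fold higher with 118 against 18 UMIs, and its log2 ratio of 3.53 became 2.81 with doublets kept. Lrp2, an endocytic receptor, was 2.86-fold higher and Ccn1, a matrix protein, 2.82-fold. Maob was 3.54-fold higher, but its log2 ratio of 1.79 became 0.53 in thinned nuclei. Lrp2 and Maob lead the visceral endoderm-like cluster. Cd27 was 7.30-fold lower, Lrfn2 6.28-fold, Cfap97d2 4.68-fold and Ism1, a secreted protein, 4.61-fold, or 6.03-fold, 5.18-fold, 3.87-fold and 3.80-fold under TMM. Cfap97d2 and Ism1 were also lower in KO trophoblast, by 11.2-fold and 8.09-fold. Across 12046 genes the log2 ratios of the KO and the cKO pair had a Pearson r of 0.0954 and a Spearman rho of 0.0244 in trophoblast, and 0.153 and 0.143 across 6548 genes in fetal mesoderm, where genes are not independent replicates. The median absolute log2 ratio in cKO trophoblast was 0.334, and 0.183 under TMM.

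The lists in cKO trophoblast, each relative to all genes, were led, Y-linked genes apart, by clustered protocadherins, surface proteins of the Pcdh loci that share exons, at -0.79 with 6 of 9 down and 0 up. All 4 Y-linked genes were lower, with a median log2 ratio of -9.95, or -7.12 with genes at 0 UMIs set to their bound. The wild types differed in the protocadherins by -0.56. Placental cathepsins stood at -0.34, pregnancy-specific glycoproteins and Ceacams at -0.18 with 8 of 22 down and 1 up, and prolactins at 0.17. Proliferation genes stood at -0.22, with 6 of 18 down and 0 up, against 0.59 between the wild types. Counts of members up and down are not relative to all genes, whose median was -0.30 here, so this shift adds to the counts down. Syncytium formation genes stood at 0.26, extracellular matrix at 0.20, maternally expressed imprinted genes at 0.19 with Meg3 1.72-fold higher, nutrient transport at 0.16 and cadherins and integrins at 0.13. Globins stood at 0.66, immediate early genes at 0.30 and mitochondrial transcripts at 0.19. Paternally expressed imprinted genes, DNA methylation machinery, hypoxia, angiogenesis, interferon and Rhox lists stood at 0.02, -0.02, -0.03, 0.07, -0.10 and -0.07, and the 4 genes of the early totipotent embryo at 0.59.

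In cKO fetal mesoderm, genes of blood vessel growth were lower, at -0.27 relative to all genes with 6 of 22 down and 0 up. Those counts are not relative to all genes, whose median was -0.19 in this class, so the shift adds to the count down. The endothelial receptor genes Tek and Kdr stood at 0.551 and 0.572 of wild type, or 0.619 and 0.641 under TMM. Endothelial-like nuclei made up 29.0% of the class in the cKO and 35.6% in its wild type, and the list stood at -0.25 between the wild types. Tal1, a transcription factor of blood and endothelium, was 3.73-fold lower and Csmd1 7.56-fold, whose log2 ratio of -2.80 was -1.38 in thinned nuclei. Afp, a fetal plasma protein made by visceral endoderm, was 3.33-fold higher, Col9a2 2.66-fold, and Cdk8 2.46-fold with 3747 against 2320 UMIs. Xist gave 1456 UMIs in the same cKO class, fewer than Cdk8. Whether all reads counted for Cdk8 come from that gene was not tested. Protocadherins stood at -0.58, against -0.73 between the wild types. Cathepsins stood at -0.35, Rhox genes at -0.32, pregnancy-specific glycoproteins at -0.27, immediate early genes at -0.27, nutrient transport at -0.21, hypoxia at -0.20 and prolactins at -0.12. The others were -0.11 for mitochondrial transcripts, -0.10 for DNA methylation machinery, 0.08 for interferon response, 0.18 for extracellular matrix and between -0.01 and 0.02 for imprinted, proliferation, cadherin, syncytium and globin lists.

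**Figure D4:**
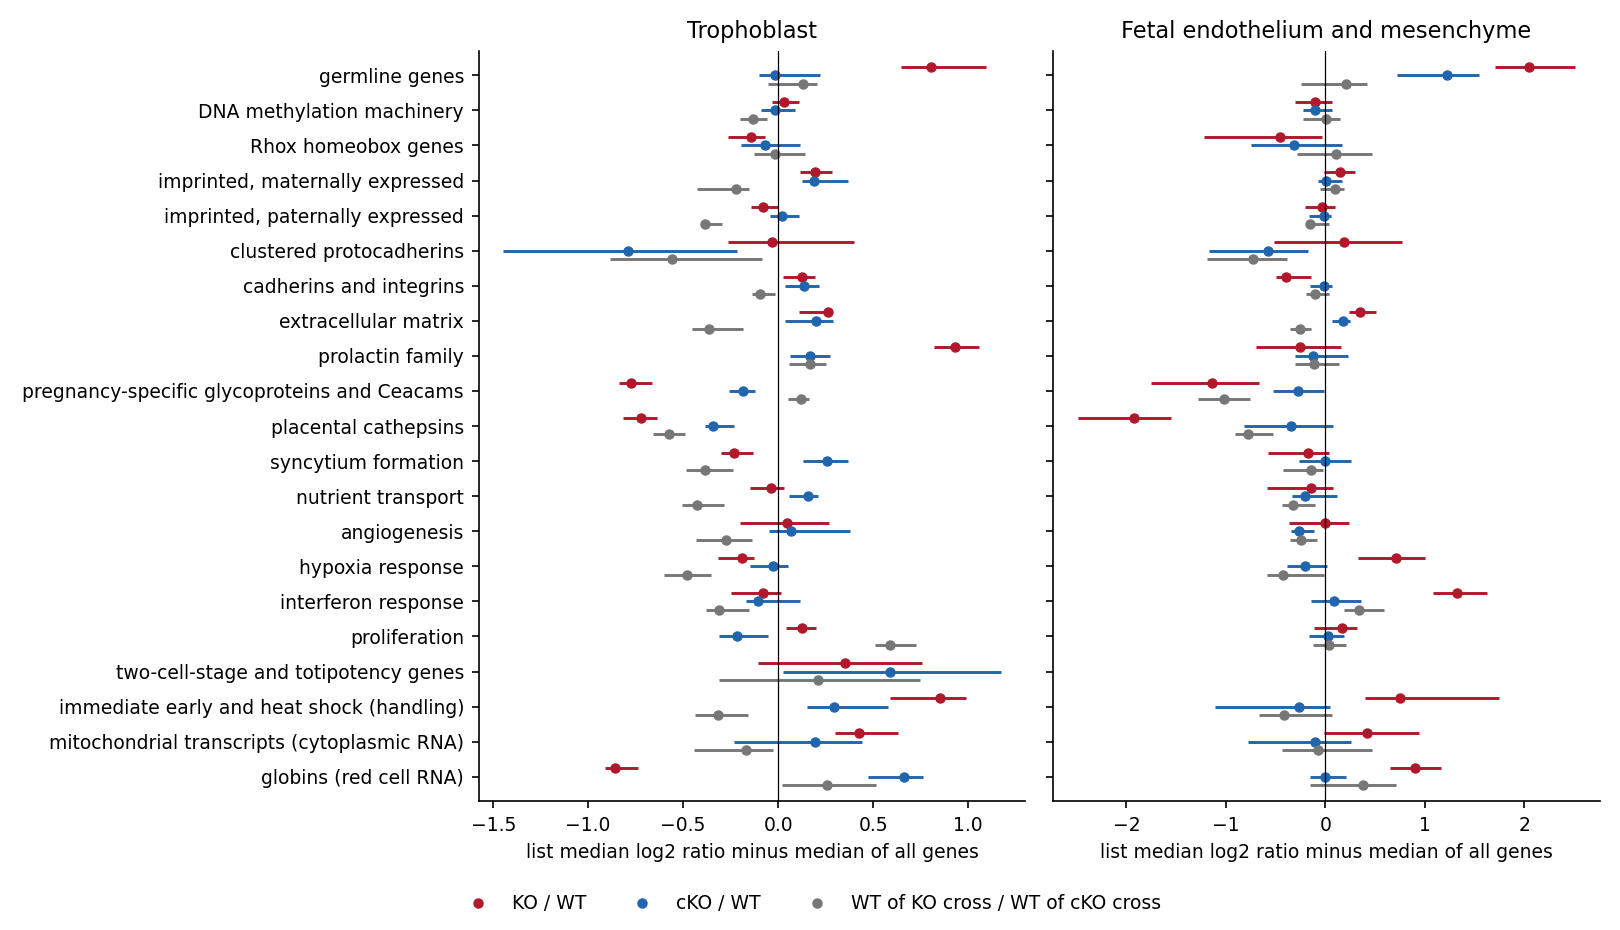
Median log2 ratio of each gene list relative to all genes, for KO and cKO over their own wild types and for wild type over wild type, in trophoblast and in fetal mesoderm, with 95% resampling intervals. Interferon response stood at 1.32 in KO fetal mesoderm and -0.08 in KO trophoblast.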

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

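The tests of explanations in this part were set up after the results they weigh had been seen, although thinned nuclei and the minimum of 500 genes had been chosen earlier as alternative settings. For sex, the bound on Y-linked counts was also changed after its outcome, from a floor of 3 UMIs to a level set beside that of the wild type, because 4 stray UMIs, at 0.00120 of the wild-type level, passed the floor. For depth, the wild types were first taken unthinned and were thinned alike after that outcome was seen.

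Germline genes were higher in the KO library in trophoblast and in fetal mesoderm. With nuclei thinned to equal UMIs, the trophoblast median stayed at 0.63 relative to all genes (0.33 to 1.14, over 19 members). Between the wild types thinned alike, the upper bounds were 0.28 over their own 17 members and 0.15 over the same members. Some of the same members held as few as 2 UMIs over the wild types. The difference thus stayed at equal depth. Ratios of summed CPM depend little on depth per nucleus, however, so thinning is a weak test of depth as the whole cause. Free trophoblast RNA in fetal mesoderm is argued against for the list, since the level in mesoderm over that in trophoblast had a median of 1.79 over 34 germline genes and 0.0977 over 44 trophoblast transcripts, but for Dazl, at 28.8 CPM in mesoderm and 93.9 CPM in trophoblast, it stays open. A few germ cells are argued against by the 46.6% of KO trophoblast nuclei with a Dazl UMI, and by Dazl intervals above the wild type in 9 of 9 clusters. Release from methylation is a hypothesis that these data may fit, and RNA alone does not test it.

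Germline genes as a list were higher in cKO fetal mesoderm and not in cKO trophoblast. Depth stays open. In thinned nuclei the median was 1.08 (0.44 to 1.59, over 7 members), above the bound of 0.16 between the wild types over the same members but not above that of 0.99 over their own 3 members. Some of the same members held as few as 2 UMIs over the wild types. For free RNA from trophoblast, the median was -0.019 in trophoblast itself, beside 1.22 over fewer members in mesoderm. Free RNA adds the level in trophoblast and not its ratio, so these medians alone cannot exclude a larger load in the cKO library. Trophoblast transcripts argue against such a load, since they were not higher in cKO mesoderm. Relative to all genes, prolactins stood at -0.12, pregnancy-specific glycoproteins and Ceacams at -0.27 and cathepsins at -0.35. Fetal sex cannot be told apart from genotype, because the cKO library lacked Y-linked transcripts. Of 9 members at least 1.5-fold higher, 8 were also higher in the KO pair, where both libraries held Y-linked reads, but no value within the cKO pair separates sex from genotype.

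Trophoblast and fetal mesoderm both held smaller shares in the KO library. More maternal decidua could account for the whole trophoblast difference, since among fetal nuclei trophoblast was 7.72 percentage points higher in the KO. The same explanation is argued against for fetal mesoderm, which was -4.61 points apart among fetal nuclei. Nuclei with few genes are argued against too, since with a minimum of 500 genes the difference was -3.51 points. Uneven dissection or loss of nuclei, and an effect of the mutation, stay open and were not tested.

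Cadherins and integrins had KO medians on opposite sides of all genes, at 0.13 in trophoblast and -0.39 in fetal mesoderm. Hypoxia response genes did so at -0.19 and 0.71, and globins at -0.86 and 0.90. The differences between the classes were not tested. Extraembryonic endoderm, which was not among the classes chosen for comparing gene levels, had a KO germline median of 1.12 relative to all genes, above the value between the wild types.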

How the results depend on the processing

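No paired analysis was possible because each group has 1 library. With a minimum of 500 genes per nucleus, the KO difference in trophoblast share moved from -6.89 to -12.6 percentage points and the KO spread, the median absolute log2 ratio over trophoblast genes, from 0.214 to 0.210. Nuclei named as trophoblast then rose from 1056 to 1169 in the KO and from 1527 to 1911 in its wild type, as fewer stayed unnamed. As a share of fetal nuclei, an alternative chosen after seeing the data, the KO difference reversed to 7.72 and the cKO difference moved from -16.3 to -10.6. The move follows from the denominator and does not show why the shares differ. Under TMM the spreads became 0.209 in the KO and 0.183 in the cKO, where the main value was 0.334, and the germline median in cKO trophoblast moved from -0.32 to -0.043. With at least 1 UMI over the pair the spreads became 0.357 and 0.485, because genes with few counts entered. Standardising the cluster mix gave a KO spread of 0.183. In thinned nuclei the cKO spread was 0.343, and the germline medians in trophoblast were 0.67 in the KO, from 0.86, and -0.41 in the cKO. Leaving Malat1 and Gm42418 out of totals, chosen after seeing the data, gave a cKO spread of 0.198. Autosomal members alone, likewise chosen later, gave a KO germline median of 1.53 in trophoblast. Where the main interval excluded 0, values also reversed for Rhox genes in KO trophoblast when thinned (0.084), proliferation genes in KO trophoblast with a standardised mix (-0.036) and genes of the early totipotent embryo in cKO trophoblast when thinned (-0.43). Prolactins in KO fetal mesoderm, whose main interval spans 0, moved from -0.25 to 1.36 with doublets kept. Except where named, the cause was not tested. The other 44 of 48 germline values, 759 list values and 679 values of ranked genes stayed within their intervals, while 54 list values and 41 gene values moved outside them. Germline medians in fetal mesoderm ranged from 1.95 to 2.36 in the KO, apart from 2.51 in thinned nuclei, where 3 members were measured in place of 16, and from 0.83 to 1.19 in the cKO. Depth limits fetal mesoderm most, with 556153 UMIs in the KO.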

Other observations

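Interferon-response genes differed in the maternal decidua of the cKO pair. Their median log2 ratio was -0.87 relative to all genes, with 13 of 16 members at least 1.5-fold lower, against 0.15 in the KO pair. Over all measured decidual genes, the median absolute log2 ratio was 0.177 in the cKO pair and 0.335 between the wild types, the latter with a shift of all genes. Other lists were lower there too, with immediate early and heat shock genes, a sign of handling, at -0.28 with 3 of 8 down and 0 up, and proliferation genes at -0.46. Genes named here were chosen after their values were seen. Rsad2, an antiviral enzyme, gave 23 UMIs in the cKO library and 75 in its wild type, a log2 ratio of -1.83. Oas1a, a sensor of double-stranded RNA, stood at -1.68 and Zbp1, a sensor of Z-form nucleic acids, at -2.00. Stat1, the signal transducer of the pathway, stood at -0.74 with 375 and 567 UMIs. In KO fetal mesoderm the same list stood at 1.32 relative to all genes.

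Decidua of the KO pair showed little germline signal as a list, with a median of 0.04. Dazl stood there at 2.73 CPM, beside 3.19 CPM for Ddx3y, a Y-linked gene that maternal cells lack, and both stood higher in KO trophoblast, at 93.9 and 74.6 CPM. Prolactins were higher in KO decidua, with a median of 0.59 relative to all genes, and Prl4a1 stood at 23.6 CPM and 2.88 CPM. Cathepsins at -1.27, pregnancy-specific glycoproteins and Ceacams at -1.03 and globins at -1.08 were lower. How far these decidual lists differed between the wild types is not given here. Over all decidual genes the median absolute log2 ratio was 0.161 in the KO pair, less than the 0.335 between the wild types. NK and lymphoid nuclei made up 3.42% of the KO library and 2.46% of its wild type, and 3.09% and 1.46% in the cKO pair. Erythroid nuclei made up 3.67% and 7.87% in the KO pair, and 0.565% and 0.580% in the cKO pair. Clusters left unnamed held 6.73% of nuclei in the KO library and 12.6% in its wild type.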
